A study of Mus musculus with 1 sample.

How the data were processed

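Gene expression was measured on 1 single-colour Affymetrix mouse array, hybridised with biotin-labelled cRNA made from total RNA of ovarian surface epithelium cells of wild-type mice aged 10 weeks. The animals had a mixed background, mostly C57BL/6, per the labels. The series text describes a comparison of cells of 2 genotypes. Cells of 1 genotype are covered here and the other is not analysed here, so no contrast between genotypes, no replicate error and no test between groups is given, and every statement below describes this array alone.

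The deposited values are intensities, 1 per probe set (a group of short probes for a transcript), on a linear scale and rounded to whole numbers. The submitters' processing notes name RMA and the R package affy; the version, the settings and the set of arrays normalised together are not given in the sources used here. RMA corrects each array for background, sets arrays to a common distribution and summarises probes on a log2 scale, so these linear values appear to have been taken back from that scale, which could not be checked from 1 array. Rounding is coarse for the dimmest probe sets: at an intensity of 5, 1 rounding step spans 0.29 on the log2 scale. The plan, fixed before the data were examined, had assumed log2 values, and log2 of the intensity was used in their place. The file carries no detection p-value. It had no sample column other than the 1 used.

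Probe sets were named through GEO's platform annotation. Of 45037 probe sets that are not controls, 34945 had 1 gene symbol, 932 had several and 9160 were unnamed in the annotation used; no gene was named from a probe set with several symbols. The Entrez identifiers of 34741 of the 34945 were matched to a RefSeq gene table of the mouse assembly GRCm38.p6, and 0 symbols had changed. No coordinates are given, since no genome build belongs to these values. A gene's value was the highest log2 intensity among its probe sets, which gave 18193 genes, of which 9010 had at least 2 probe sets.

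The background level was the 95th percentile of 84 probe sets of 75 chemosensory receptor genes (olfactory, vomeronasal, taste and trace amine receptors), which are silent in most tissues. A gene was called above background when its value exceeded that level. A set of 35 gene lists (cell type markers, pathways and positive or negative references) was fixed before the data were examined. They held 566 members, of which 500 had a probe set of their own, and 66 are not analysed here. The median of each list was placed among the medians of 10000 random gene lists of the same size and the same numbers of probe sets per gene (6 or more counted together, genes drawn with replacement, seed 1). A list was called high at or above percentile 97.5 and low at or below the 2.5th. Were all 35 lists random draws of genes, about 1.75 would lie outside these bounds. They are not random draws, and the references among them were chosen to lie high or low. The percentile describes this array and is no p-value, because genes are not replicates. Intervals of a list's median are exact 95% binomial intervals over its members, and cover the spread between members and not that between animals.

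The rule for naming genes was also fixed in advance. It took Amhr2 and 3 further genes that are not reported here, Xist, each measured steroid receptor or receptor partner of the list, the 4 members with the highest and up to 2 with the lowest value of every other list, and the 10 genes with the highest value on the array outside ribosomal genes, genes of the mitochondrial genome and the housekeeping list. Genes outside the rule are marked as chosen after their values were seen. Probe sets differ in affinity, so the value of one gene does not rank its transcript against another gene's.

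The list statistic was tested on simulated data, with the values of the 18193 genes shuffled among genes of equal probe set number and 10 lists of 20 genes raised. At a raise of 3.0 on the log2 scale 9 of 10 lists were called high, at 2.0 it was 6, at 1.0 it was 2 and at 0.5 it was 0; of the unchanged lists, 2 of 10 were called at the 0.5 setting and 0 of 10 at each of the others. Alternatives covered the background level (the 99th percentile, tissue-restricted genes, a level that rises with the number of probe sets, the median probe set), the value of a gene (mean or lowest probe set), probe sets that can bind several transcripts, the matching of random lists, the list mean, and genes held by several lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.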

Results

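Ovarian surface epithelium is the single layer of mesothelium-like cells that covers the ovary. The transcriptome of such cells from wild-type mice was profiled on 1 array, with no replicate, so values carry no replicate error and the number of arrays limits their precision. The series was designed to set these cells beside those of a second genotype, which is not analysed here. Over the 45037 probe sets that are not controls, intensity ranged from 5 to 27929, with a median of 41 and quartiles of 15 and 238. The background level was an intensity of 36.7 (5.20 on the log2 scale), against a median of 11.5 for the chemosensory receptor probe sets that set it. Of 18193 named genes, 12323 (67.7%) had a value above it, and 5 of the 75 chemosensory genes did. That low count follows from how the level was set. Where the 95th percentile of tissue-restricted genes (hepatocyte, photoreceptor, pancreas, muscle, neuron and sperm genes) set the level instead, it was 79.2, and 10166 genes (55.9%) exceeded it. Genes between 36.7 and 79.2 are therefore described as near background.

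**Figure D1:**
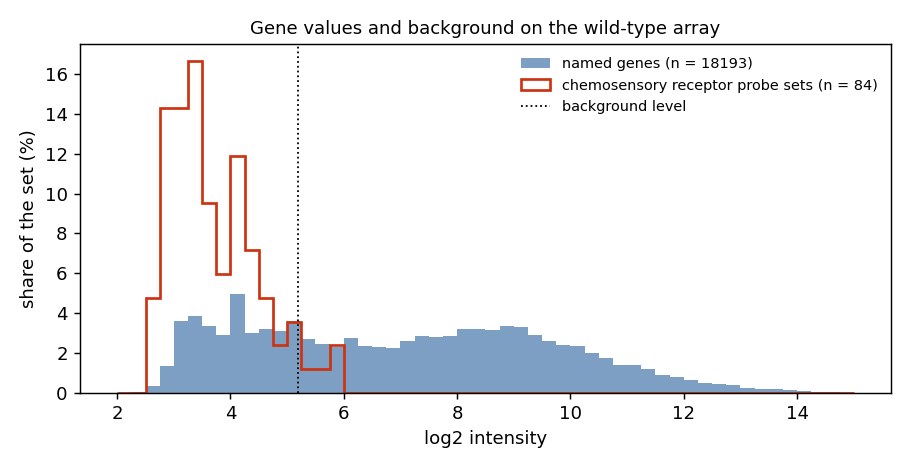
Histogram of log2 intensity (x axis) as the share of each set in percent (y axis) for 18193 named genes (filled) and 84 chemosensory receptor probe sets (outline), with the background level of 5.20 dotted. The chemosensory probe sets lie at the low end of the gene distribution, and 67.7% of genes lie above the dotted line.

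The array was first set against its label. Xist, the RNA that coats the inactive X chromosome of female cells, was above background in each of its 3 probe sets, at 305, 1099 and 4001. Of 15 probe sets of Y-linked genes, 14 were at or below background, with a median intensity of 12 over all 15. Eif2s3y, a Y-linked translation factor gene, read 9 and Uty, a Y-linked demethylase gene, read 12. The exception was 1 of the pair of probe sets of Sry, the testis-determining gene, which was near background at 70 while the other read 7. Among the controls, the 3′ probe set of Actb read 1.39 times the 5′ probe set, and that of Gapdh 0.961 times. Some other controls gave larger ratios, 3.40 for Pcx (170 against 50), 4.00 for Tfrc (36 against 9, both below background) and 18.9 for the spiked bacterial dap transcript (756 against 40), while that of cre was 1.16. The bacterial and phage hybridisation controls BioB, BioC, BioDn and CreX read 81, 630, 1280 and 9124 in their 5′ probe sets. Of 16 ribosomal protein genes, 16 were above background, with a median of 12700, and of 12 housekeeping genes 12 were, with a median of 7315.

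Markers of ovarian surface epithelium and mesothelium were detected almost throughout, with 22 of 23 measured members above background and a median of 3569 (11.80 on the log2 scale, interval over members 10.74 to 12.37). That median exceeded those of all 10000 random lists, whose centre was 6.66. The uroplakins Upk3b and Upk1b, membrane proteins of mesothelium and urothelium, read 18226 and 15980. Ezr, whose protein links actin to the membrane in microvilli, read 9616 and Krt7, a simple-epithelium keratin, read 8897. Gata4, a transcription factor of the gonad, read 348, and Pkhd1l1, at 15, was the member below background. All 22 also exceeded the level set by tissue-restricted genes.

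Genes of epithelial junctions had a lower median. Of 16 measured members 14 were above background, but 7 exceeded the tissue-restricted level, and the list median of 49.2 lay at percentile 9.30, within the range of random lists, and at 9.30 to 49.7 under the 6 alternative ways of placing a list. The claudin gene Cldn3 read 2780, the desmosomal plakophilin Pkp2 read 2610, the tight-junction scaffold Tjp1 read 1099 and Epcam, an epithelial adhesion molecule, read 280. Cldn7 and Esrp1, an epithelial splicing regulator, were below background at 22 and 13. Chosen after their values were seen, the cadherin genes Cdh1 (E-cadherin) and Cdh2 (N-cadherin) read 38, which is near background, and 3513.

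Stromal and contractile genes were detected together with the surface markers. All 16 measured stroma and fibroblast genes were above background, with a median of 1742, above every random list. The collagen genes Col1a2 and Col3a1 read 23690 and 15071, the matrix protein gene Sparc read 22010 and the proteoglycan gene Dcn read 12298, while Mfap5 read 180 and Fbln1 read 61, near background. Of 10 smooth muscle and pericyte genes, 8 were above background and the median was 2820, also above every random list. Smooth muscle actin Acta2 read 18406, the actin-binding Tagln 16724, the myosin kinase Mylk 4435 and the enteric actin Actg2 3732, whereas the mural cell genes Notch3 and Rgs5 were below background at 36 and 15. When the lowest probe set of each gene was taken, this list's median fell to percentile 79.2. Mesenchymal and epithelial-mesenchymal transition genes were above background in 15 of 17 cases, led by the intermediate filament gene Vim at 13774, the integrin Itgav at 6946, the cadherin Cdh11 at 6881 and the gelatinase Mmp2 at 5203, with Mmp9 at 35 and Snai1 at 34 below it. That list lay at percentile 97.6, just past the bound, and fell short of it under 3 of 6 alternatives, to percentile 71.1 when probe sets were averaged. All 13 basement membrane genes were above background, with Col4a1 at 13131, Col4a2 at 7924, the laminin Lamb1 at 2373 and the nidogen Nid2 at 2073, and Col18a1 and Lama1 at 98 and 97. Their median lay at percentile 98.4, and short of the bound under 2 of 6 alternatives (96.6 with averaged and 96.2 with lowest probe sets).

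Markers of the other ovarian cell types were detected to different extents. Oocyte genes were low as a list, with 3 of 15 above background, 0 of 15 above the tissue-restricted level and a median of 15 at percentile 0.46. Zar1, Gdf9 and Nlrp5, genes active in the growing oocyte, read 70, 64 and 52, near background, the oocyte transcription factor gene Nobox read 33, and the germ cell genes Dazl and Ddx4 read 10 and 8. Oviduct epithelium genes were also low, with 4 of 12 above background and the median at percentile 2.25; Rsph1, a component of motile cilia, read 160, Pax8, Ovgp1 and Cdhr3 were near background at 63, 53 and 38, and Dnah9 and Fam183b each read 13. That list left the low range with averaged and lowest probe sets (3.54 and 4.11). All 13 measured granulosa genes were above background and 9 exceeded the tissue-restricted level, with the median of 589 at percentile 97.2, short of the bound, and past it under 4 of 6 alternatives (97.52 to 98.9). The connexin gene Gja1 read 9112, Amhr2, the receptor of anti-Müllerian hormone, read 4501, and the inhibin and activin subunit genes Inhba and Inhbb read 1777 and 1112. Fshr, the receptor of follicle-stimulating hormone, and Hsd17b1, an estradiol-forming enzyme, were near background at 39 and 40. Chosen after their values were seen, Inha read 589 and Foxl2 read 575, while Amh and Nr5a2 were near background at 68 and 45. Foxl2 and Inhba each had 2 probe sets, and the other probe set of each was below background. Of 8 theca and luteal genes 6 were above background, with the median at percentile 83.0, and past the bound under 1 of 6 alternatives. The ferredoxin gene Fdx1 read 1766, the cholesterol transporter Star 1670, the steroid dehydrogenase Hsd3b1 810 and the lipoprotein receptor Scarb1 566, whereas Cyp17a1, needed for androgen synthesis, and Ptgfr, the prostaglandin F receptor, read 23 and 31.

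Leukocyte genes, chiefly those of macrophages, were above background in 14 of 17 cases, and all 14 exceeded the tissue-restricted level. Their median of 521 lay at percentile 99.8. The lysozyme gene Lyz2 read 8297, the macrophage growth factor receptor Csf1r 2231, the complement gene C1qb 1179 and the signalling adaptor Tyrobp 1140. The T cell gene Cd3e and the B cell gene Cd79a were below background at 34 and 19. So was the macrophage gene Mrc1 at 36, chosen after its value was seen. Endothelial genes were above background in 4 of 11 cases, with Esam, an adhesion molecule, at 1752, the VEGF receptor Kdr at 683, Egfl7 at 111 and the VEGF receptor Flt1 near background at 79, and the endothelial genes Tie1 and Emcn at 10 and 7. Their median of 21 lay at percentile 3.89, within the range of random lists, and at 1.89 against unmatched random lists, past the low bound. Of 5 measured red blood cell genes 0 were above background, the heme synthesis gene Alas2 reading 28, Slc4a1 28, Epb42 22, and the globin genes Hbb-b2 and Hba-a1 14 and 13. Probe sets shared by several globin genes are not in that count. They read 159 and 90, above both background levels, and 30 and 10, below them. Of 8 adipocyte genes 4 were near background, Plin4 at 69, Lipe at 59, Fabp4 at 52 and Retn at 49, and Adipoq and Cidec read 11 each. The red blood cell and adipocyte medians lay at percentiles 6.04 and 8.79, and each past the low bound under 2 of 6 alternatives.

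**Figure D2:**
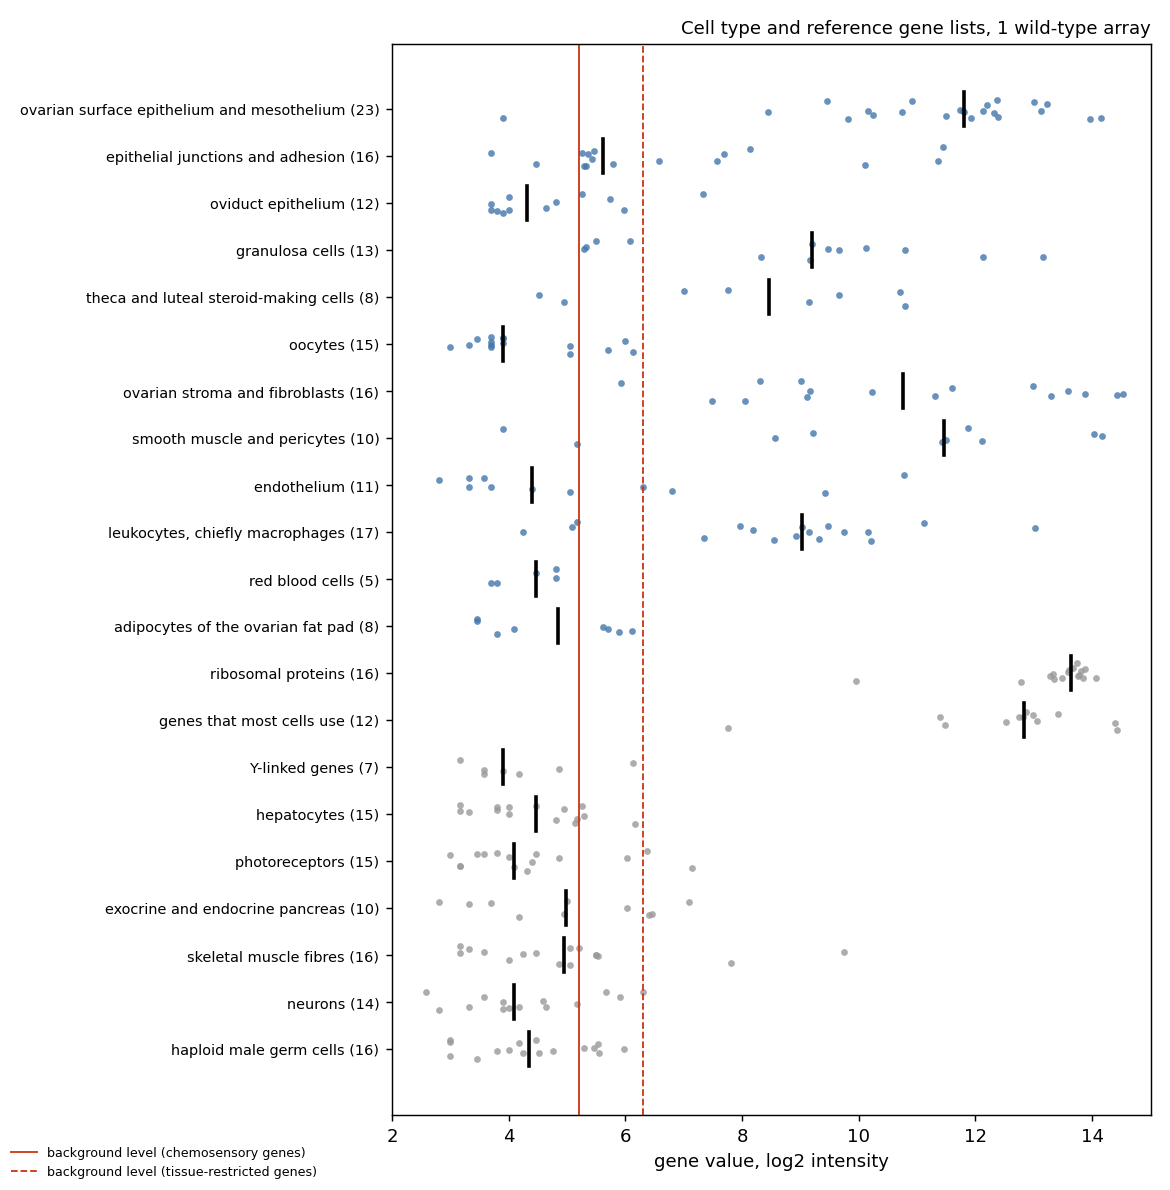
Log2 intensity (x axis) of each measured gene (points) of the cell type lists (blue) and the positive and negative reference lists (grey), with the list median as a black bar, the number of measured genes in brackets, and the 2 background levels of 5.20 (solid) and 6.31 (dashed). The surface epithelium, stroma, smooth muscle and leukocyte lists have medians to the right of both lines, at 11.80, 10.77, 11.46 and 9.03. So do the granulosa and theca lists, at 9.20 and 8.45. The oocyte list, with its median at 3.91, lies to the left of both lines.

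Steroid hormones are named in the series title, and their receptors and partners were examined singly. Of 16 measured members 13 were above background and 12 exceeded the tissue-restricted level; the list median of 418 lay at percentile 86.5. The estrogen receptor gene Esr1 read 636 and Esr2 read 21, below background. The progesterone receptor Pgr read 509 and the glucocorticoid receptor Nr3c1 read 357, while Nr3c2, the mineralocorticoid receptor, was near background at 48. The progesterone-binding membrane proteins Pgrmc1 and Pgrmc2 read 7458 and 899. Nr5a1, a regulator of steroid synthesis genes, read 370 and Nr0b1, its repressor, read 15, and the membrane estrogen receptor Gper1 read 21. The receptor chaperones Fkbp5 and Fkbp4 read 1290 and 575, the coactivators Ncoa2, Ncoa1 and Ncoa3 read 458, 381 and 190, and Greb1, an estrogen-induced gene, read 912. Probe sets disagreed for many of these genes: with the lowest probe set of each, 4 of 16 remained above background, and Esr1, Pgr, Nr3c1, Nr5a1 and Greb1 were among those at background. Of 17 genes that estrogen or progesterone induce in reproductive tissues, 15 were above background, among them Hif1a at 5189, Igf1 at 1544 and Sgk1 at 840, with Ihh and Cited1 at 25 and 20. That list lay at percentile 96.5, within the range of random lists, at 98.6 against random lists not matched on probe sets, past the bound, and at 76.7 without genes held by several lists. With the lowest probe set of each gene it lay at percentile 60.4, with 8 of 17 above background.

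Target genes of p53, a protein that the series title also names, were examined next. All 22 measured members were above background, 20 exceeded the tissue-restricted level, and the median of 900 exceeded that of every random list. With the lowest probe set of each gene, 17 of 22 were above background. The cyclin gene Ccng1 read 4126, the antiproliferative gene Btg2 4123, the stress-response gene Ddit4 3826 and the cell cycle inhibitor Cdkn1a 3778. Rprm and Tnfrsf10b, a death receptor gene, were near background at 64 and 39. Of 12 measured family members and regulators of p53, 11 were above background, and 7 and 5 with averaged and lowest probe sets. The deubiquitinase Usp7 read 1308, the ubiquitin ligase Mdm2 1033, Cdkn2a 618 and Mdm4 327. Trp73 was near background at 39 and Trp63 read 23. That list lay at percentile 30.6, and at 20.8 to 70.0 under the 6 alternatives. All 15 measured Ras and PI3-kinase genes were above background, among them Map2k1 at 2307, the phosphatase gene Dusp6 at 2224, Gsk3b at 1081 and Akt1 at 949, and Foxo1 and Etv4 at 284 and 134. Their median lay at percentile 91.3, and past the bound under 2 of 6 alternatives.

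Cell cycle genes were above background in 20 of 21 cases, with a median of 570 at percentile 98.7. The replication clamp gene Pcna read 3419, Ube2c and Cdc20, which act in mitotic exit, read 1284 and 1256, and the replicative helicase gene Mcm6 read 1111. Aurkb read 118, and the thymidylate synthase gene Tyms was below background at 11. Immediate early and stress genes, which respond within minutes to handling of cells, were above background in 18 of 19 cases at percentile 99.9, with Ier3 at 5072, Jun at 3359, Egr1 at 2535 and Jund at 1895, Nr4a1 at 131 and Fosb at 14. A list of AMH, BMP and activin receptors, SMADs and the target genes Id1, Id2 and Id3 was above background in 15 of 16 cases and lay at percentile 99.98. Id3 and Id1 read 6554 and 3150, the receptor Bmpr1a read 2930, Acvr2b was near background at 53 and Bmpr1b read 24.

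Wnt pathway genes were above background in 16 of 16 cases, and the median lay at percentile 96.2, short of the bound. It passed the bound under 3 of 6 alternatives, and with the lowest probe set of each gene it lay at percentile 26.5 with 7 of 16 above background. Beta-catenin, Ctnnb1, read 10576, the Wnt agonist Rspo1 1920, Wnt4 1587 and the receptor Fzd1 1076, with Lef1 and Wnt7a near background at 71 and 66. Among retinoid genes 11 of 14 were above background, with the retinaldehyde dehydrogenases Aldh1a1 and Aldh1a2 at 15366 and 3889, Dhrs3 at 1496 and Rdh10 at 1247, and Rbp4 and Crabp1 at 32 and 12, and the median at percentile 80.1. Of 14 complement and cytokine genes 12 were above background; C1s1 read 12707, Saa3 6631, Ccl2 2028 and Ptgs2 1818, while Lcn2 and Cxcl5 read 26 and 15. That list lay at percentile 98.98, but fell short of the bound under 5 of 6 alternatives (85.9 to 96.0). Interferon-stimulated genes were above background in 8 of 13 cases, at percentile 33.6, with Oasl2 at 1122, Bst2 at 344, Ifit2 at 151 and Psmb8 at 130, and Usp18 and Mx1 at 14 and 9.

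**Figure D3:**
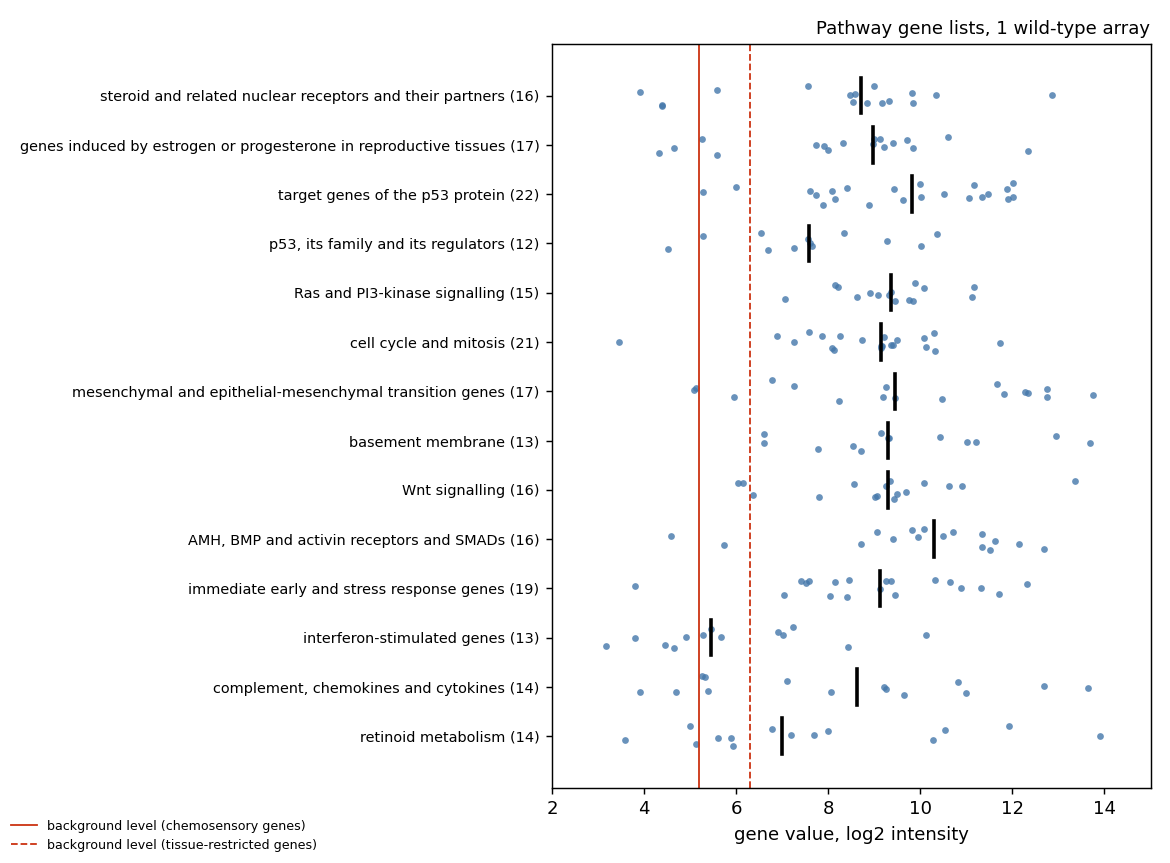
Log2 intensity (x axis) of each measured gene (points) of the 14 pathway lists, with the list median as a black bar, the number of measured genes in brackets, and the 2 background levels of 5.20 (solid) and 6.31 (dashed). The p53 target list has its median at 9.81 with all 22 points to the right of the solid line, and the interferon list has its median at 5.46, between the lines.

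Of the 35 lists, 13 were high, 6 were low and 16 lay between the bounds. Among the negative references, 3 of 15 hepatocyte, 3 of 15 photoreceptor, 4 of 10 pancreas, 6 of 16 skeletal muscle, 3 of 14 neuron and 5 of 16 sperm genes were above background, with list medians of 17.0 to 31.5. The 6 low lists were the oocyte and oviduct lists and the Y-linked, photoreceptor, neuron and sperm references. The genes with the highest values on the array outside ribosomal genes, genes of the mitochondrial genome and the housekeeping list were Lgals1 at 27929, Tpt1 at 23965, Col1a2 at 23690, Tsc22d1 at 22344, Sparc at 22010, Cox6a1 at 21864, Tmsb10 at 21094, Tmsb4x at 20505, Fth1 at 19018 and Pabpc1 at 18507. This order is one of signal and not of transcript number. Among the 9010 genes with several probe sets, the highest and lowest probe set of a gene differed by a median of 2.42 on the log2 scale (quartiles 1.09 and 4.33), and in 4114 of them (45.7%) the probe sets fell on both sides of the background level.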

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

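The count of genes above background fell from 12323 to 8209 when the lowest probe set of each gene was taken. The 6 other settings gave 10166 to 11916. All 7 settings raised the level, lowered gene values or left out probe sets. Each could therefore only lower this count and that of list members. List members above background numbered 365 of 500, and 251 to 352 under the 7 alternatives. Lists outside the bounds numbered 19, and 15 to 27 under the 6 alternatives; no list so called changed direction. The surface epithelium, stroma, leukocyte, p53 target, cell cycle, AMH and BMP, immediate early, ribosomal and housekeeping lists were high under all 6. The smooth muscle list left the high range with the lowest probe set only (percentile 79.2). The mesenchymal, basement membrane and complement lists left it when probe sets were averaged (71.1, 96.6 and 95.9) and under 2, 1 and 4 further settings. The granulosa list entered it without shared probe sets (98.9), with unmatched random lists (98.4), with list means (98.4) and without genes in several lists (97.52). The Wnt list entered it in the first 3 of these settings (97.54, 99.6 and 97.9), the Ras and PI3-kinase list with unmatched random lists and list means (99.4 and 97.8), the steroid response list with unmatched ones (98.6) and the theca list with the lowest probe set (99.4). The low range was entered by the adipocyte, red blood cell and hepatocyte lists with averaged probe sets (2.37, 2.38 and 0.98) and list means (0.55, 0.40 and 0.03), the pancreas and skeletal muscle lists with list means (1.70 and 0.28), and the endothelial and hepatocyte lists with unmatched random lists (1.89 and 0.98). The oviduct list left the low range with averaged probe sets (3.54) and lowest probe sets (4.11). Of 226 named genes 166 were above background; 17 of these fell to it with averaged probe sets and 51 with the lowest, and 4 of 160 without shared ones, the cause being untested per gene. The background level itself moved from 5.20 to 5.21 without shared probe sets. Signal over background limits weak genes: with the tissue-restricted level the epithelial junction count went from 14 to 7 and the granulosa count from 13 to 9. No paired analysis was possible because only 1 array was analysed.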

Other observations

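Some genes of the tissue-restricted negative references were above background. Actn3, an actinin of fast muscle fibres, read 864, and Acta1, skeletal actin, read 224, while 10 of 16 skeletal muscle genes were at or below background. Abca4, a photoreceptor transporter gene, read 142, and the pancreatic genes Ctrb1 and Ins2 read 136 and 88. Of 15 hepatocyte genes 3 were near background, Ttr at 72, Apoa2 at 39 and Apoa1 at 38. Of the 9160 probe sets without a gene name, 1896 (20.7%) were above background, against 52.3% of all probe sets that are not controls.

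For the following patterns the tests were chosen after the patterns had been seen. Second marker lists were written before their values were looked up, except that 2 of the granulosa genes and 1 blood gene had been seen. The members named from these lists, other than Esr2, fall outside the naming rule and were chosen after their values were seen. The bounds were fixed before. A list had to have 75% of its measured members above background and a median in the range of high lists to bear an explanation out, and an interval of the share (exact, over genes, which are not replicates) wholly under 75% to count against it. Missing the range of high lists does not by itself count against an explanation, since markers of a minor cell type need not reach it. Over all named genes the share above background was 67.7%. No biological explanation from the design was tested, since 1 genotype was analysed.

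Macrophage markers such as Lyz2 at 8297 were above background. The tables argue against blood carried over as their source: of 15 measured lymphocyte and neutrophil genes 5 (33.3%, interval 11.8 to 61.6) were above background, the neutrophil genes S100a8 and S100a9 at 23 and 18, and the 5 near background included Cd8a at 75 and Cd4 at 67. Macrophages in the preparation remain a candidate explanation. Of 19 genes of a second macrophage list 17 (89.5%, interval 66.9 to 98.7) were above background, Ctss at 2643 and Mpeg1 at 985 leading. Among the 17, Pld4 at 74, Spi1 at 68, Clec4n at 56, Aif1 at 53 and Lyve1 at 37 were near background. The macrophage genes Itgam and Cd163 were below background at 22 and 8. The median of 125 lay at percentile 55.0 of random lists, so the full condition was not met. Surface epithelial cells that transcribe some of these genes stay open as well and were not tested. Globin probe sets shared by several genes, at up to 159, leave a trace of blood possible.

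The contractile genes Acta2 and Tagln read 18406 and 16724 while Rgs5 and Notch3 were below background. Of 15 genes of actin fibres and serum response 15 (100%) were above background, with a median of 2593 above every random list, Tpm4 at 10172, Tpm2 at 10127 and Ankrd1 at 1192. Fibroblasts and smooth muscle express these genes too, so the list does not separate an actin and serum response programme of the surface cells from the other explanations, and its test decides nothing. Vessel wall cells were neither borne out nor excluded at this background level, with 6 of 12 genes (50%, interval 21.1 to 78.9) above it, and a median of 39.7 at percentile 13.0. Foxs1 read 407 and Higd1b read 14. Of the 6, Cspg4 at 70 and Cox4i2 at 45 were near background, so the outcome may depend on the level. Differentiated smooth muscle also stayed open, with 9 of 11 genes (81.8%, interval 48.2 to 97.7) above background but a median at percentile 28.1. Jph2 read 514, and Synpo2, Myocd and Kcnmb1 were near background at 73, 40 and 38.

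Granulosa cells as a source of the granulosa markers could not be decided. Of 12 genes of a second list 6 (50%, interval 21.1 to 78.9) were above background, Trib2 at 649 and Gatm at 478, with Esr2 at 21 and Slc26a7 at 15. Of the 6, Tnni3 at 47 and Nppc at 40 were near background, so the outcome may depend on the level. The median of 32.9, below background, lay at percentile 11.6, outside the high range, but the interval of the share reaches past 75%. Expression of Amhr2, Gja1 and Inhba by surface cells would also give their values and may be the alternative. Inha and Foxl2 of the first list, at 589 and 575, were above background as well, while Amh and Nr5a2 of that list were near background at 68 and 45. The RNA of 1 array cannot separate these sources.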
